A study of Homo sapiens with 5 samples.

How the data were processed

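HT1376 human bladder carcinoma cells were given DMSO or 250 nM CPI-0209 for 8 days and fixed with formaldehyde, and ChIP-seq with antibodies against EZH2 and H3K27me3 was run by a service provider, per the labels. The labels also speak of cells treated for 4 days and of an antibody against acetylated H3K27, and no list named for either was analysed here. The series has 5 samples, of which 4 ChIP libraries (EZH2 DMSO, EZH2 CPI-0209, H3K27me3 DMSO and H3K27me3 CPI-0209, 1 library per group) have an interval list and 1 input library was not used here. BWA, SICER and hg38 are named in the submitters' processing notes without version, role or settings. Whether the input served as the control of the calls is not given in the sources used here.

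The deposited lists hold, per the file headers, the chromosome, start and end of each interval and nothing else, so there is no score, count, fold or p-value to rank or filter by, and the depth of the libraries is unknown. An interval is a yes or no call: its absence from a list does not show that the mark was absent, and a library with fewer reads or more background yields fewer and narrower calls of the same domains. Every start and every width (end minus start plus 1) was checked to be a whole multiple of 200 bp, and all intervals lie on the 22 autosomes and the X chromosome. Intervals within a list overlap, with at most 2 over any position; 44516 intervals over the 4 lists overlap an earlier one of their list. What each list combines is not stated. Stretches under 2 intervals were therefore also counted on their own, a choice made after the overlaps were seen. They made up 62.7% of the covered length for H3K27me3 DMSO, 12.9% for H3K27me3 CPI-0209, 17.8% for EZH2 DMSO and 50.8% for EZH2 CPI-0209. Starts in the lists count from 0; coordinates are printed counting from 1.

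Retained length is the percent of the base pairs covered in the DMSO list that the CPI-0209 list also covers, and a retained interval overlaps an interval of the other list by at least 1 bp. Domains are overlapping intervals merged. Percents of intervals and genes have exact (Clopper-Pearson) 95% binomial intervals and percents of length have bootstrap intervals from 1000 draws of 10 Mb blocks. These cover counting error or the spread over the genome within the libraries, neighbouring intervals and genes are not independent, and none of them measures the spread between cultures. The share of EZH2 intervals on H3K27me3 was set beside 1000 circular shifts of the H3K27me3 intervals along each chromosome, which keep widths and spacing and can place them in assembly gaps.

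Genes came from a RefSeq gene table of GRCh38.p14, the assembly of hg38, with 59098 gene records on these chromosomes, 19974 of them protein-coding. The plan was a promoter window of 2 kb either side of each gene's start, but the table gives no strand. The windows were therefore laid at both ends of the gene record. A gene with both ends marked has a marked promoter at its outermost start. For such promoters this count is a lower bound, and the count of genes with at least 1 end marked is an upper bound. Starts inside a gene record were not scored. A gene was called kept with both ends marked in both lists, lost with both in DMSO and neither in CPI-0209, partly kept with both and then 1, and gained with neither and then both. Long genes seldom have both ends in 1 domain. Exons and introns were not told apart, since no exon table was used here, so location is given as near gene ends, within gene bodies or intergenic.

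The 21 gene lists were fixed before the data were examined, as were the main comparisons and most alternatives. The gene lists hold HOX genes, other developmental regulators, signalling, tumour suppressor, urothelial, keratinocyte and other tissue markers, immune, chromatin and control genes. The plan did not hold the split of H3K27me3 retention by EZH2 and by domain width, or the domain widths at kept genes. Nor did it hold the random draws for kept and lost list members. All listed genes matched the table, by symbol or older symbol. Each list's count was set beside 10000 random lists of as many protein-coding genes, and its kept and lost members beside random draws from genes marked in DMSO. The draws for kept and lost members were not matched on gene length. These percentiles describe the libraries and are no test of the treatment. Cells of other types are not expected in a cell line, and no cell type was named from the marker lists. Genes named in the text were the 8 per class with the widest intervals, 1 gene per interval, the first 4 members of a list for each outcome described, all members of lists of 12 or fewer genes, the PRC2 list, and the 5 longest intervals per library. Widths printed at a gene are those of the widest merged domain that touches 1 of its end windows. Other names were chosen after their values were seen, among them HOX cluster coverage, lost members past the first 4, pairs picked to illustrate EZH2 at lost genes, and the gene families, noncoding genes and keratin region.

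Alternatives changed 1 choice at a time: intervals at or above the median width of each list (the lists hold no score to choose a stricter set by), intervals of at least 1 kb, the longer list of each pair shortened to the covered length of the shorter one by keeping its widest intervals, gaps under 5 kb joined, an overlap of at least 50% of the interval, end windows of 1 kb and 5 kb, and windows at least 50% covered. Stretches under 2 intervals, merged intervals, both gene ends, shifts within 1 Mb blocks that hold an interval, random lists matched on gene length, random draws matched on quintile of DMSO domain width, and all alternatives for the ratio of covered lengths were added after the data were seen.

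The calculations were tested on simulated data. Removing known parts of the 21589 merged H3K27me3 DMSO domains gave back all 6 planted percents with a largest difference of 0 percentage points, and 200 of 200 genes with planted intervals were found. In 200 shifts of the DMSO H3K27me3 intervals, the number of the 18637 merged EZH2 DMSO domains that they met was counted. Of these counts 11 lay above 95% of those from other shifts, where 10 are expected. Both sets came from the same kind of shift, so a value near 10 follows from the design. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9 were used.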

Results

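HT1376 is an established human bladder carcinoma cell line. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on HT1376 cells given the vehicle DMSO or 250 nM CPI-0209, an inhibitor of EZH2, for 8 days. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3, and its trimethylated product H3K27me3 marks repressed chromatin. One antibody was against EZH2 and the other against H3K27me3, which gave 4 ChIP groups with 1 library each. The labels list 1 input library as well, and no interval list of it was analysed here. Each ChIP library is represented by a list of called intervals in hg38 coordinates without scores or read counts, so sequencing depth is unknown. With 1 library per group the differences between DMSO and CPI-0209 had no replicate check, and no test between the conditions was possible. Limits in brackets are 95% limits; they cover counting error or, for lengths, the spread over blocks of the genome, within the libraries at hand.

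The first comparison asked how much of the H3K27me3 landscape of DMSO cells was still called in CPI-0209 cells. H3K27me3 intervals covered 315.1 Mb in DMSO and 113.8 Mb in CPI-0209, a ratio of 0.361 (log2 −1.47, −1.58 to −1.37). Of the DMSO length, 35.8% (33.2 to 38.4) was also covered in CPI-0209, and 99.2% (99.1 to 99.3) of the CPI-0209 length lay inside DMSO intervals. The covered length was lower in CPI-0209 on 23 of 23 chromosomes, with ratios from 0.211 on the X chromosome to 0.456 on chromosome 9. Of the 41342 DMSO intervals, 20591 (49.8%, 49.3 to 50.3) overlapped a CPI-0209 interval by at least 1 bp. The retained DMSO intervals had a median width of 11.8 kb and the others 5.6 kb. Among 18865 CPI-0209 intervals only 189 had no DMSO counterpart, with a median width of 1.4 kb. Of 21589 DMSO domains, formed by merging overlapping intervals, 12724 had no CPI-0209 domain, 5828 had 1 and 3037 had 2 or more. Stretches covered by 2 overlapping intervals of the same list measured 197.5 Mb in DMSO and 14.7 Mb in CPI-0209, a ratio of 0.0746 (log2 −3.75). Counted over such stretches alone in both lists, the retained share was 7.43%. Of the DMSO length under 2 intervals, 54.5% was covered by at least 1 CPI-0209 interval. When the DMSO list was shortened to the CPI-0209 length by keeping its widest intervals, the retained share was 59.2% of length and 97.8% of intervals.

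**Figure D1:**
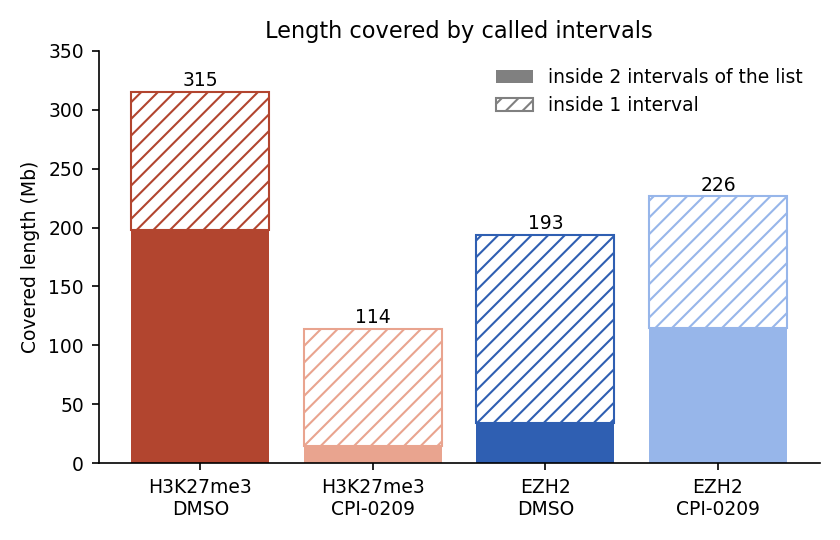
Length of the genome (Mb, vertical axis) covered by the called intervals of each of the 4 libraries, with 1 library per bar. Filled parts lie inside 2 overlapping intervals of the same list and hatched parts inside 1; the H3K27me3 total was 315.1 Mb in DMSO and 113.8 Mb in CPI-0209, and the EZH2 total was 193.4 Mb and 226.3 Mb.

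EZH2 intervals were compared by the same measures. They covered 193.4 Mb in DMSO and 226.3 Mb in CPI-0209, a ratio of 1.17 (log2 0.23, 0.19 to 0.26), and the covered length was higher in CPI-0209 on 23 of 23 chromosomes, from 1.04 on chromosome 6 to 1.41 on chromosome 19. Of the DMSO length, 78.2% (75.8 to 80.2) was also covered in CPI-0209, and 66.8% (65.2 to 68.5) of the CPI-0209 length lay in DMSO intervals. Of 24311 DMSO intervals, 21879 (limits 89.6 to 90.4%) overlapped a CPI-0209 interval. The CPI-0209 list held 12358 intervals without a DMSO counterpart, 28.4% of its 43522, with a median width of 3.2 kb. EZH2 stretches covered by 2 intervals of the same list measured 34.4 Mb in DMSO and 114.9 Mb in CPI-0209, a ratio of 3.34 (log2 1.74), and stretches covered by 1 interval measured 159.1 Mb and 111.4 Mb.

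EZH2 and its mark were then set against each other within each condition. In DMSO cells 56.9% (56.2 to 57.5) of EZH2 intervals lay on H3K27me3, and in CPI-0209 cells 52.2% (51.7 to 52.6). Circular shifts of the H3K27me3 intervals along the chromosomes gave means of 16.3% and 7.57%, so the observed shares were 3.49-fold and 6.89-fold those of the shifts, and none of 1000 shifts reached either. With overlapping EZH2 intervals merged, so that each stretch counted once, the shares were 58.2% in DMSO and 41.0% in CPI-0209. These were 3.49-fold and 5.39-fold those of the shifts. Conversely, 46.2% of DMSO H3K27me3 intervals carried EZH2, against 93.9% of the H3K27me3 intervals called in CPI-0209. DMSO H3K27me3 that lay under EZH2 (139.6 Mb) was called again in CPI-0209 over 68.6% (66.7 to 70.5) of its length, and DMSO H3K27me3 without EZH2 (175.5 Mb) over 9.71% (9.05 to 10.3). The same order held where 2 H3K27me3 intervals overlapped (73.6% with EZH2 and 20.1% without) and where 1 did (18.6% and 2.73%). Width went with retention as well. Among DMSO domains of 0.2 to 4.6 kb, 11.4% (10.5 to 12.4) met a CPI-0209 interval, and among those of 19.4 kb and wider 88.0% (87.0 to 89.0) did. Within this widest group the share was 96.8% (96.2 to 97.4) with EZH2 and 43.5% (39.8 to 47.2) without. Wider domains offer more positions at which an overlap of 1 bp can occur; the share of length retained was 6.74% in the narrowest group and 50.9% in the widest.

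**Figure D2:**
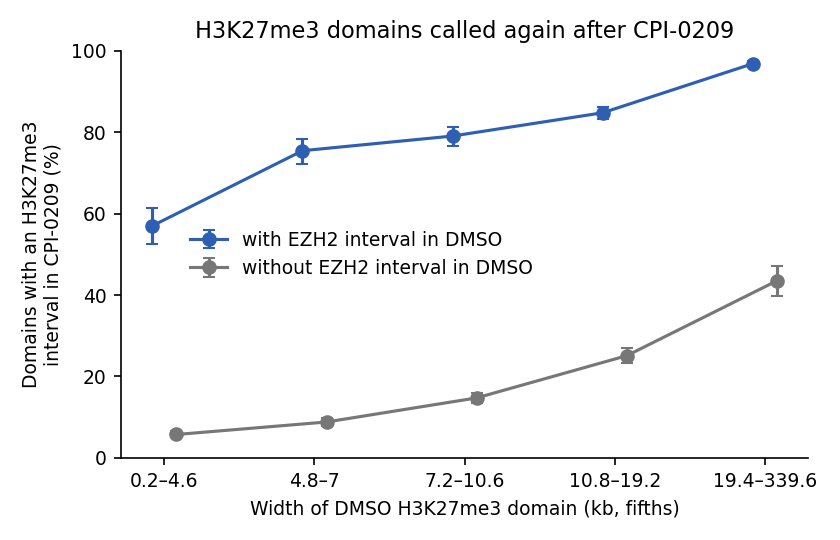
Percent of DMSO H3K27me3 domains that overlapped an H3K27me3 interval in CPI-0209 (vertical axis), for 5 groups of domain width in kb (horizontal axis), separately for domains with and without an EZH2 interval in DMSO. Bars are exact 95% binomial intervals for counting error; with EZH2 the share was 57.0% in the narrowest group and 96.8% in the widest, and without EZH2 it was 5.73% and 43.5%.

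At genes, H3K27me3 was scored within 2 kb of the ends of 19974 protein-coding gene records, because the gene table gives both ends of a gene but not its strand. A gene marked at both ends has a marked promoter at its outermost start whichever end that is, and a gene marked at neither has none there. Starts inside a gene record were not scored, so a gene without the mark means one marked at neither end. At least 1 end was marked at 6258 genes (31.3%, 30.7 to 32.0) in DMSO and 4342 (21.7%, 21.2 to 22.3) in CPI-0209, and both ends at 3029 and 1733. Of the 3029 genes, 1704 (56.3%, 54.5 to 58.0) were marked at both ends in CPI-0209 too, 823 at 1 end, and 502 (16.6%, 15.3 to 17.9) at neither. Only 9 genes had no H3K27me3 at either end in DMSO and H3K27me3 at both in CPI-0209. At the 1704 genes the widest H3K27me3 domain touching an end had a median of 39.4 kb in DMSO and 12.1 kb in CPI-0209, and it was narrower in CPI-0209 at 1662 of them. With gaps under 5 kb joined the medians were 76.8 kb and 26.5 kb, and it was narrower at 1667. The 502 genes had a median DMSO domain of 12.2 kb. Shortening the DMSO list to the CPI-0209 length by its widest intervals turned the order of the genes marked at 1 end or more (1763 in DMSO against 4342). It left 764 genes marked at both ends in both lists and 27 in DMSO alone. The cut removes narrow intervals from the DMSO list alone and can only lower its count, so the turned order is no evidence on the conditions. Over stretches covered by 2 intervals, 971 genes were marked at 1 end or more in CPI-0209, with 279 kept and 1496 lost. Lost here means without such a stretch, and at most 502 of the 1496 had no CPI-0209 interval at either end.

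By the rule of widest intervals, the genes with H3K27me3 at both ends in both conditions included RBFOX3, a neuronal splicing factor (chromosome 17, 79089345 to 79665571, overlapped by a 258.4 kb DMSO interval), LAMC3, a laminin chain, ELFN2, WFDC1, GPR20, CFAP46, SSBP3 and the uncharacterised LOC124901483, on the same interval as SOX4. Those with the mark in DMSO alone included TAF1C, SMIM35, CEP164, CDKAL1, CECR2, GDPD4, MED27 and CIMIP1. TAF1C, CEP164, GDPD4 and MED27 lay beside a wide DMSO interval rather than under it, within 2 kb of its edge. For TAF1C (chromosome 16, 84177855 to 84187057) the 258.2 kb DMSO interval from 84188801 to 84447000 is the one that also covers WFDC1. CEP164 (chromosome 11, 117321778 to 117413266) ended next to the interval from 117413801 to 117566000. In CPI-0209 alone the mark was called at both ends of PSORS1C2, PHPT1, SLC5A2, C1orf202, FZD9, B3GNT9, RHOB and LOC124901350, with CPI-0209 intervals from 10.4 kb at PSORS1C2 down to 1.60 kb at LOC124901350.

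Among the fixed gene lists, developmental regulators carried the mark in both conditions. All 39 HOX genes, which set positional identity in the embryo, carried H3K27me3 at both ends in DMSO and in CPI-0209, against means of 5.90 and 3.38 in 10000 random lists of the same size, and all 39 carried EZH2 at both ends in both. The 39 genes lie in 4 clusters on 6 merged DMSO domains and are not 39 separate events, unlike the scattered genes of the random lists. At each of the 39 the H3K27me3 domain was narrower in CPI-0209, with medians of 173.2 kb and 61.0 kb, while EZH2 domains were narrower at 18 and wider at 21 (medians of 140.6 kb and 132.4 kb). H3K27me3 covered 100% of the HOXA cluster (chromosome 7, 27092993 to 27200091) in DMSO and 93.8% in CPI-0209, in 1 and 4 pieces. The HOXC cluster (chromosome 12, 53938831 to 54056030) had 100% and 94.7%, the HOXB cluster (chromosome 17, 48528526 to 48728750) 86.7% and 61.2%, and the HOXD cluster (chromosome 2, 176087487 to 176190907) 99.2% and 66.8% in 2 and 13 pieces. Counted only over stretches covered by 2 intervals, 16 HOX genes kept the mark at both ends. Random draws of 39 genes marked in DMSO kept a mean of 21.9, and 30.5 when matched on DMSO domain width.

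**Figure D3:**
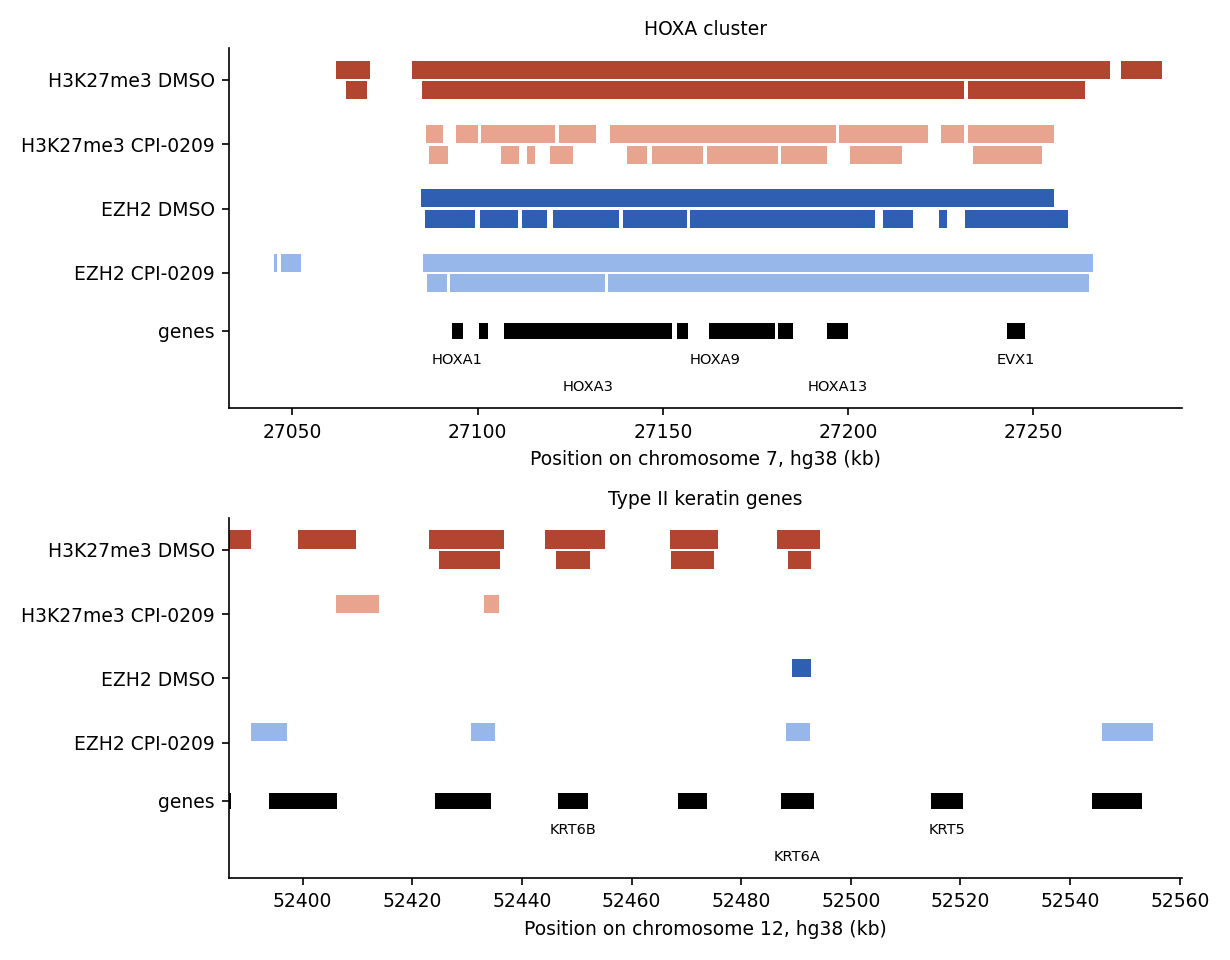
Called intervals of the 4 libraries (rows) over the HOXA cluster on chromosome 7 and the type II keratin genes on chromosome 12, with protein-coding gene records in black; positions are in kb, hg38, and overlapping intervals of a list are drawn on a second line. H3K27me3 covered 93.8% of the HOXA cluster in CPI-0209 and was not called at KRT6A and KRT6B there.

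Of 80 other developmental transcription factors, 55 carried H3K27me3 at both ends in DMSO. Of these, 49 did so in CPI-0209 as well, 6 at 1 end and 0 at neither (0 of 55 allows up to 6.49%). PAX2, GATA4, SIX2 and SIX6 were among the 49, and the domain at GATA4 measured 80.2 kb in DMSO and 8.60 kb in CPI-0209. TBX3, WT1 and ISL1 were among the 6. All 49 domains were narrower in CPI-0209, with medians of 29.0 kb and 12.8 kb. WNT, BMP, FGF and Hedgehog signalling genes gave 22 of 46 in DMSO, of which 18 were kept and 0 lost at both ends, such as WNT1, WNT3A, WNT10B and WNT11. The domain at WNT1 measured 43.4 kb in DMSO and 7.80 kb in CPI-0209. Neuronal and neuroendocrine genes gave 14 of 34, with 11 kept, including NEUROG2, INSM1 and NCAM1, and 1 lost, CHGB. Muscle genes gave 8 of 15, with 6 kept, including MYOD1, MYF5, MYOG and DES, and 1 lost, MYF6. The domain at MYOD1, the myogenic regulator, measured 56.8 kb and 8.80 kb. Each of these lists, like the HOX genes, had more marked members than at least 99.9% of random lists in both H3K27me3 libraries. Random draws of 55 genes marked in DMSO kept a mean of 31.0, and 31.7 when matched on DMSO domain width, against the 49 developmental factors. Against the 18 signalling genes these means were 12.4 and 13.0. For the 11 neuronal genes they were 7.88 and 7.27, and for the 6 muscle genes 4.49 and 4.26 (75.5% and 81.9% of draws lower). No draw was matched on gene length. Over all protein-coding genes, median gene length was 9.95 kb for kept, 24.5 kb for partly kept and 7.55 kb for lost genes. With the DMSO list shortened to its widest intervals, 21 of the developmental factors and 9 of the signalling genes were marked in both conditions, and over stretches covered by 2 intervals 17 and 3 were. With at least 50% of the window covered, 10 signalling genes were.

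Other tissue lists differed in how many of their marked members were still marked. Among basal and squamous keratinocyte genes, 5 of 27 carried H3K27me3 at both ends in DMSO, and KRT6A, KRT6B, PI3 and S100A7 had none at either end in CPI-0209. KRT6A and KRT6B are stress-induced keratins (chromosome 12, 52487176 to 52493257 and 52446651 to 52452146), PI3 is the protease inhibitor elafin, and S100A7 is psoriasin. LORICRIN was marked in both conditions. Losing 4 of 5 (28.4 to 99.5%) was more than in 99.6% of random draws of 5 marked genes, and more than in 89.6% of draws matched on DMSO domain width, with means of 0.843 and 2.13 lost. Antigen presentation and interferon response genes gave 5 of 39, with 3 lost, namely HLA-B and the chemokines CXCL9 and CXCL11, 1 marked at a single end, HLA-DPA1, and 1 kept, CCL5. Losing 3 of 5 was more than in 96.4% of random draws and 91.9% of draws matched on domain width, with means of 0.840 and 1.24 lost. The DMSO domains at CXCL9 and CXCL11 measured 10.6 kb and 10.8 kb, and neither gene had EZH2 in either condition. Olfactory receptors gave 38 of 392, of which 25 (65.8%, 48.6 to 80.4) had no H3K27me3 at either end in CPI-0209, against a mean of 6.31 in random draws and of 10.8 in draws matched on domain width, and 6 were kept. None of these draws was matched on gene length. With the DMSO list shortened to its widest intervals, 1 olfactory receptor, 0 keratinocyte genes and 0 antigen presentation genes were marked in DMSO alone; with at least 50% of the window covered, 1 antigen presentation gene was.

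For urothelial luminal genes, 3 of 25 were marked at both ends in both conditions, UPK1A, FOXA1 and TBX2. UPK1A encodes a uroplakin of the bladder surface, FOXA1 is a luminal transcription factor, and its domain measured 22.6 kb in DMSO and 9.40 kb in CPI-0209. Mesenchymal genes gave 7 of 28, with 6 kept, including TWIST1, TWIST2, COL1A1 and COL5A1. Blood cell genes gave 8 of 20, with 3 kept (HBA1, IKZF1 and PAX5), 4 marked at 1 end and 1 lost, CD79A, and liver genes gave 4 of 14, with 2 kept (APOA1 and HNF4A) and 1 lost, TTR. Cell cycle inhibitors and tumour suppressors gave 5 of 26, with CDKN1C, RUNX3, DAB2IP and GADD45G kept and SLIT3 marked at 1 end. CDKN2A and CDKN1A had no H3K27me3 at either end in both conditions. Natural killer cell ligands gave 4 of 12. MICB and ULBP1 were kept, ULBP2 and RAET1L were marked at 1 end in CPI-0209, ULBP3 at 1 end in both, and CD48 at 1 end in DMSO alone. MICA, RAET1E, RAET1G, NCR3LG1, PVR and NECTIN2 carried none. Protocadherin clusters gave 15 of 53, with 9 kept and 3 lost (PCDHB11, PCDHB14 and PCDHB15). Zinc finger genes gave 24 of 517, below each of the 10000 random lists, with 9 kept and 5 lost (ZNF660, ZNF713, ZNF556, ZNF444 and ZNF835). Ribosomal protein genes gave 1 of 80 (RPL38, kept), PRC1 genes 3 of 19, with CBX2 and CBX8 kept and CBX6 marked at 1 end, and SWI/SNF subunits 2 of 21, ACTL6B and DPF3, both marked at 1 end in CPI-0209. No housekeeping gene of 35 and no gene of the PRC2 and H3K27 demethylase list (14 genes) had H3K27me3 at both ends in either condition.

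**Figure D4:**
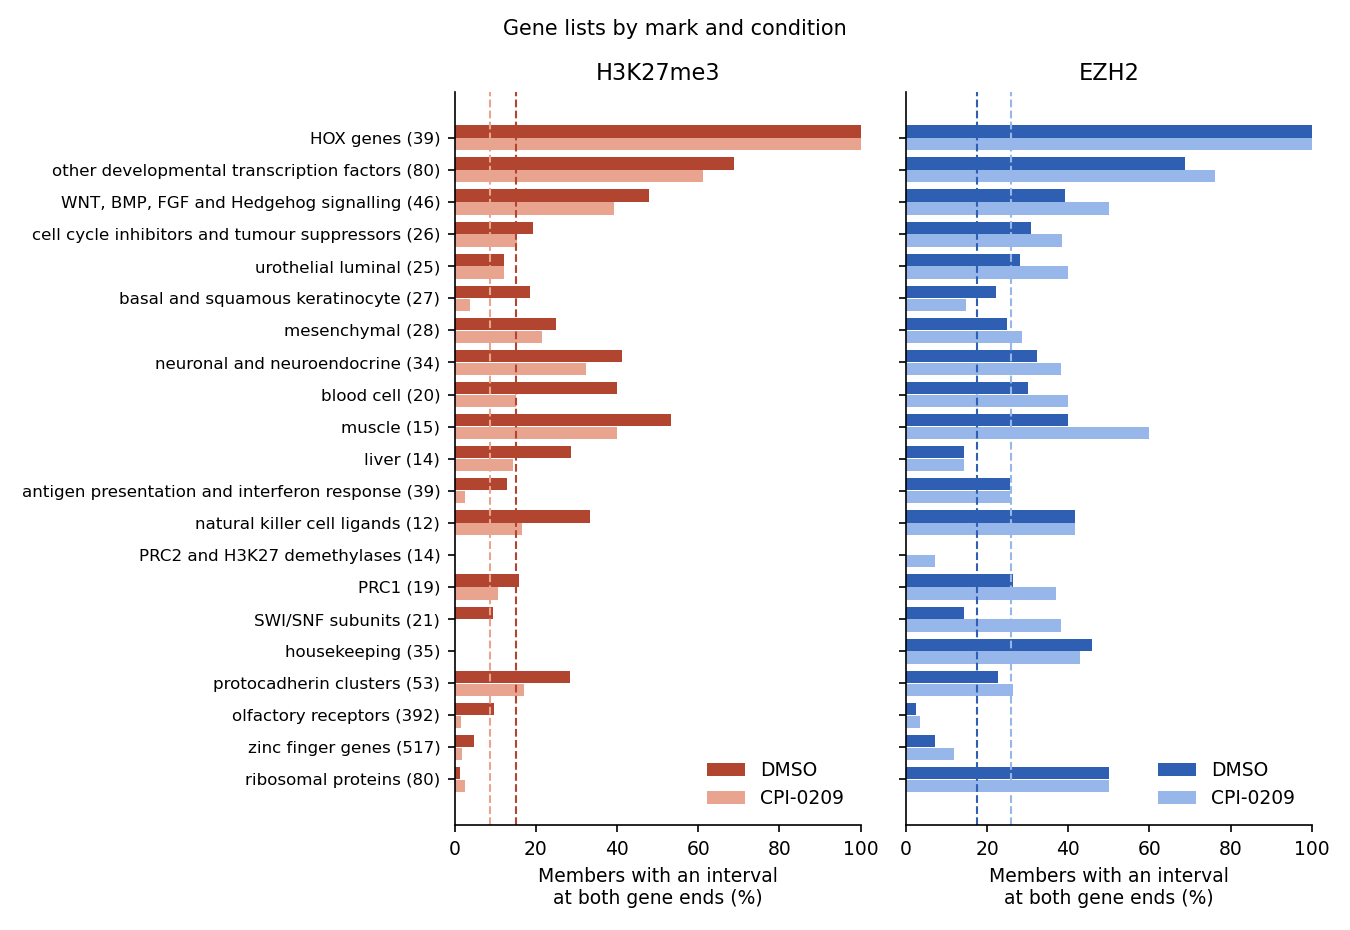
Percent of the members of each of 21 gene lists (members in brackets) with an interval within 2 kb of both gene ends (horizontal axes), for H3K27me3 and EZH2 in DMSO and CPI-0209; dashed lines give all protein-coding genes, and each bar is 1 library without error bars. HOX genes were at 100% in all 4 libraries, and ribosomal protein genes were at 1.25% for H3K27me3 and 50% for EZH2 in DMSO.

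EZH2 was called at more genes than its mark, except in DMSO over stretches covered by 2 intervals (4625 genes with EZH2 and 4959 with H3K27me3). At least 1 end carried EZH2 at 10904 genes (54.6%, 53.9 to 55.3) in DMSO and 14276 (71.5%, 70.8 to 72.1) in CPI-0209, and both ends at 3489 and 5179. Of the 3489, 3067 (87.9%, 86.8 to 89.0) had EZH2 at both ends in CPI-0209 and 52 (1.49%) at neither, while 825 of 9070 genes without EZH2 in DMSO (9.10%, 8.51 to 9.71) had it at both ends in CPI-0209. By the rule of widest intervals, the latter included SOCS1, a feedback inhibitor of cytokine signalling (chromosome 16, 11254417 to 11256204, under a 214.4 kb CPI-0209 interval), PDGFRB, a growth factor receptor, FNDC11, NACC2, ESS2, FAAH, ADCK5 and LOC124901482. Genes with EZH2 in both conditions included COL4A2, a basement membrane collagen, CIITA, the activator of MHC class II genes, LAMC3, ELFN2, GABRD, GPR20, HOXA10 and LOC124901483. EZH2 in DMSO alone was called at CASQ1, NIT1, MKNK1, ZNF689, MED8, H2AC14, OR2B2 and TMEM186. With the CPI-0209 list shortened to the DMSO length by its widest intervals, the order turned, at 10904 genes in DMSO against 7432. EZH2 was then lost at both ends of 526 genes and gained at both ends of 446. The cut removes narrow intervals from the CPI-0209 list alone and can only lower its count. The turned order is therefore no evidence on the conditions.

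EZH2 was also called at genes without H3K27me3. Among 35 housekeeping genes it lay at 1 end or more of 29 in DMSO and 35 in CPI-0209, including ACTB, GAPDH, TUBA1B and TUBB, where H3K27me3 was called at 1 gene in DMSO (PSMB2, outside the naming rule and chosen after its value was seen) and at 0 in CPI-0209. Of 80 ribosomal protein genes, 71 had EZH2 in DMSO and 71 in CPI-0209, 62 and 66 of them without H3K27me3 at either end. Over stretches covered by 2 intervals, 18 housekeeping and 41 ribosomal protein genes had EZH2 in DMSO, and with intervals at or above the median width 36 ribosomal protein genes did. Cell cycle inhibitors and tumour suppressors had EZH2 at 24 of 26 genes in DMSO and 26 in CPI-0209, 15 and 17 of them without H3K27me3, including CDKN2A, CDKN2B, CDKN1A and CDKN1B. In the PRC2 and H3K27 demethylase list it was called at 6 of 14 genes in DMSO and 11 in CPI-0209. The gene EZH2 itself, EED, JARID2, MTF2, RBBP4 and KDM6B had it at 1 end or more in both, EZH1, PHF1, PHF19, RBBP7 and KDM6A in CPI-0209 alone, and SUZ12, AEBP2 and EZHIP in neither. H3K27me3 lay at 1 end of PHF19 in DMSO and of KDM6B in both conditions.

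EZH2 was then examined at the genes where H3K27me3 was no longer called. Among the 502 genes with the mark at both ends in DMSO and at neither in CPI-0209, 29.5% (25.5 to 33.7) had EZH2 at 1 end or more in DMSO and 54.2% (49.7 to 58.6) in CPI-0209. HLA-B, KRT6A, PCDHB11, CHGB and CD79A had EZH2 in both conditions, MYF6 in CPI-0209 alone, and KRT6B, PI3, S100A7 and TTR in neither. Among the 1704 genes with H3K27me3 in both conditions the shares were 96.4% (95.4 to 97.2) and 99.6% (99.2 to 99.9). Genes without H3K27me3 in either condition (13628) had 45.3% (44.4 to 46.1) and 63.9% (63.0 to 64.7), so EZH2 was called at more genes in CPI-0209 in all 3 groups. With EZH2 required at both ends the 502 genes had 12.9% and 28.9%, and with intervals at or above the median width the genes that lost the mark had 49.5% and 61.4%. These shares were not recomputed with lists of equal covered length. Over stretches covered by 2 intervals, 1496 genes no longer had such an H3K27me3 stretch, and at most 502 of them had no CPI-0209 interval at either end. Of the 1496, 28.01% had EZH2 covered by 2 intervals in DMSO and 81.8% in CPI-0209. Such stretches made up 17.8% of the EZH2 length in DMSO and 50.8% in CPI-0209, and the shares were not separated from that difference.

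Sequence within 2 kb of the end of a protein-coding gene made up 9.12% of the H3K27me3 length in DMSO, 14.4% in CPI-0209, 20.5% of the EZH2 length in DMSO and 21.4% in CPI-0209, against 5.68% of the megabase blocks that held an interval. Intergenic sequence made up 37.6%, 31.1%, 28.9% and 28.4%. The H3K27me3 length called in DMSO alone (202.2 Mb) had 6.31% near gene ends and 41.3% in intergenic sequence. The longest H3K27me3 interval in DMSO lay on chromosome 6 from 21238001 to 21551200 (313.2 kb), between CDKAL1 and SOX4 and over no protein-coding gene, and 60.4% of it was covered in CPI-0209. The next, from 21580401 to 21851000, held SOX4, and 40.6% of it was covered. The others were on chromosome 17 from 79087001 to 79345400 with RBFOX3 and ENGASE, on chromosome 16 from 84188801 to 84447000 with KCNG4, WFDC1 and ATP2C2 among its genes, and on chromosome 22 from 37230801 to 37486800 with RAC2, CYTH4, ELFN2 and MFNG. In CPI-0209 the longest H3K27me3 interval measured 138.4 kb, on chromosome 9 from 135669001 to 135807400 with SOHLH1 and KCNT1. The next 4 held CYTH4 and ELFN2, COL4A1 and COL4A2, GPR20 and PTP4A3, and NTNG2. The longest EZH2 interval overlapped an end of CDKAL1 (chromosome 6, 20534457 to 21232404) in both conditions and lay mostly beyond the gene. It ran from 21192801 to 21551000 (358.2 kb) in DMSO and from 21153801 to 21551000 (397.2 kb) in CPI-0209. The next EZH2 intervals in DMSO held COL4A1, COL4A2 and RAB20, then CIITA and its neighbours, SOX4, and LAMC3. Those in CPI-0209 held SOX8, SSTR5 and CACNA1H among their genes, then SOX4, SOCS1 with the protamine genes, and LOC124901483.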

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

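The tests in this part were chosen after the results were seen. H3K27me3 and EZH2 differed in opposite directions under the same treatment: the log2 ratio of covered length in CPI-0209 over DMSO was −1.47 for H3K27me3 and 0.23 for EZH2. The direction was the same on 23 of 23 chromosomes for each target. The difference between the targets was not tested, since each value rests on 1 library per condition, and chromosomes of a library are not replicates.

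A difference lying only in stretches under a single interval is argued against for H3K27me3. Its stretches covered by 2 overlapping intervals had a CPI-0209 over DMSO ratio of 0.0746, and those under 1 interval 0.842. The first ratio also falls where 2 intervals give way to 1. Of the DMSO length under 2 intervals, 54.5% still had at least 1 CPI-0209 interval, and the other 89.8 Mb had none. For EZH2 these ratios were 3.34 and 0.700, so its total length rose in stretches covered by 2 and not in those under 1. The ratios do not show where the added EZH2 length lay. Of the CPI-0209 EZH2 length, 75.1 Mb lay outside the DMSO list, and only 10.6 Mb of that was covered by 2 intervals. The EZH2 length new in CPI-0209 thus lay mostly under 1 interval. Of the 114.9 Mb under 2 intervals in CPI-0209, 104.3 Mb lay in stretches that the DMSO list also covered. The ratio of 3.34 therefore does not argue against a gain of covered length mainly under 1 interval. A lower sensitivity of calling in the CPI-0209 H3K27me3 library, through depth or background, could give fewer and narrower intervals inside the same domains and stays open: 99.2% of the CPI-0209 length lay inside DMSO intervals, and the lists hold no counts with which to check it. Treatment with CPI-0209 may account for the difference too, and EZH2 was called again at 130 of the 148 genes (87.8%, 81.5 to 92.6) that lost H3K27me3 and had EZH2 in DMSO, against 95.2% of all genes with EZH2. It was called in CPI-0209 alone at another 142 of the 502 genes that lost the mark, and at more genes without H3K27me3 in either condition as well, 63.9% against 45.3%. Library and treatment cannot be told apart with 1 library per group.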

How the results depend on the processing

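None of the alternatives below turned the sign of a log2 ratio of covered lengths. Stretches under 1 interval, not counted among them, had a lower EZH2 length in CPI-0209 (ratio 0.700, log2 −0.514). Of 142 alternative values of the main results, 89 stayed within their interval or within 1.5 times the main count and 53 did not; of 62 values for single gene lists, 47 did and 15 did not. The 89 and the 47 include values that a setting could not change, such as those of the list left uncut at equal covered length. Retained length on every chromosome, the same by definition, is also among the 89. The 62 include means of random draws. No paired analysis was possible because each group has 1 library, which also rules out leaving a replicate out. Not run were random placement outside runs of N and random lists matched on GC content, for want of a genome here. Lists of equal covered length were also not used for EZH2 intervals on H3K27me3 or for EZH2 at genes that lost H3K27me3. Nor were they used for gene list counts beside random lists. The ratio of covered lengths was not recomputed with lists of equal covered length, which fixes it, and the lists hold no chromosome beyond those used. Depth is unknown and limits every absence of a call. Causes were not tested unless stated; wider intervals, more overlap or fewer intervals follow from several settings' own construction.

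At or above the median width, 81.2% of EZH2 intervals were retained, 71.9% of DMSO and 57.4% of CPI-0209 EZH2 intervals lay on H3K27me3, and 2710 genes had H3K27me3 in CPI-0209, with EZH2 at 5960 in DMSO and 6771 in CPI-0209. EZH2 was lost at both ends of 162 genes, and of genes that lost H3K27me3, 49.5% had EZH2 in DMSO and 61.4% in CPI-0209.

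With equal covered length, by construction on the widest intervals of the longer list, retained length was 59.2% for H3K27me3 and 70.4% for EZH2, and retained intervals 97.8% and 60.9%. Genes with H3K27me3 in DMSO numbered 1763 and with EZH2 in CPI-0209 7432, which turned the order of conditions for both. The cut can only lower the count of the list it shortens, so the turned order is no evidence on the conditions. H3K27me3 was lost at 27 genes and kept at 764, and EZH2 gained at 446 and lost at 526.

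With gaps under 5 kb joined, EZH2 retained length was 80.3% and its length ratio 0.26 (log2); retained intervals were 44.6% for H3K27me3 and 86.7% for EZH2, and EZH2 intervals on H3K27me3 52.4% in DMSO and 37.7% in CPI-0209. With overlapping intervals merged, these 4 were 41.1%, 87.5%, 58.2% and 41.0%. With an overlap of at least 50% of the interval they were 29.9%, 80.9%, 55.3% and 43.2%.

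With stretches covered by 2 intervals only, in both lists, H3K27me3 retained length was 7.43%, and the log2 length ratios were −3.75 for H3K27me3 and 1.74 for EZH2. Genes with H3K27me3 in CPI-0209 numbered 971, and with EZH2 4625 in DMSO, fewer than the 4959 with H3K27me3, and 7116 in CPI-0209. H3K27me3 was lost at 1496 genes and kept at 279, and EZH2 was lost at 98. Of genes that lost H3K27me3 by this count, 81.8% had EZH2 covered by 2 intervals in CPI-0209. Lost here means without a stretch covered by 2 intervals, so a single CPI-0209 interval can remain.

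With windows at least 50% covered, 1116 genes kept H3K27me3, 85 lost EZH2, and 35.7% of genes that lost H3K27me3 had EZH2 in DMSO. With both gene ends required, H3K27me3 was at 3029 genes in DMSO and 1733 in CPI-0209, and EZH2 at 3489 and 5179; of genes that lost H3K27me3, 12.9% and 28.9% had EZH2 at both ends in DMSO and CPI-0209. Shifts within 1 Mb blocks gave 2.95-fold for EZH2 on H3K27me3 in DMSO.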

Other observations

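Gene families and gene types below, and all tests in this part, were chosen after the data were seen. Among 26 symbol families with at least 10 genes marked by H3K27me3 at both ends in DMSO, NKX homeobox genes kept the mark at 12 of 12 and collagen genes (COL) at 13 of 16, with 0 lost. Keratin-associated protein genes (KRTAP), which encode hair proteins, kept it at 24 of 25, although these genes share 12 merged intervals and are not 24 separate events. Chemokine genes of the CCL family lost it at 7 of 12, and olfactory receptor genes at 25 of 38. By the count used for the KRTAP genes, those 38 lay on 34 merged intervals, and by a separate count their end windows touched 39. Cytochrome P450 genes (CYP) kept it at 6 of 19 and lost it at 2. Of genes with H3K27me3 at both ends in DMSO, 66.8% of 358 miRNA genes, 63.1% of 157 tRNA genes, 47.8% of 3347 lncRNA genes, 36.1% of 2461 pseudogenes and 29.2% of 113 snoRNA genes kept it at both ends, against 56.3% of protein-coding genes. The shares with neither end marked in CPI-0209 were 32.7%, 36.3%, 29.3%, 59.8% and 70.8%, against 16.6%. These differences were not tested, and a short gene, whose end windows overlap, seldom has only 1 end marked, so that both of its shares can exceed those of longer genes. Genes of the imprinted snoRNA clusters SNORD115 and SNORD116 on chromosome 15 and SNORD113 and SNORD114 on chromosome 14 had no record with both ends marked in any of the 4 libraries. EZH2 lay at both ends of 64.1% of 443 tRNA genes in DMSO, and H3K27me3 at 35.4%.

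EZH2 intervals without H3K27me3 lay near gene ends more often than those on it. In DMSO 68.8% of the 10488 intervals off H3K27me3 lay within 2 kb of the end of a protein-coding gene, against 42.5% of the intervals on it and a mean of 15.5% in shifts of all EZH2 intervals. Of the intervals off the mark 81.0% were called again in CPI-0209, and of those on it 96.8%. The EZH2 length called in CPI-0209 alone (75.1 Mb) lay in DMSO H3K27me3 domains for 56.6% and in CPI-0209 H3K27me3 for 16.2%. For the EZH2 length called in both conditions these shares were higher, 81.8% and 61.6%. For the length called in DMSO alone they were lower, 37.7% and 7.35%. The most covered megabase of H3K27me3, chromosome 17 from 79000001 to 80000000, was the same in DMSO (92.1%) and CPI-0209 (71.1%), with RBFOX3 and the PRC1 genes CBX2 and CBX8 inside.

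At housekeeping and ribosomal protein genes, EZH2 was called without its mark: H3K27me3 was called at 8.85% (4.33 to 15.7) of these 113 genes in DMSO, against 31.3% of all protein-coding genes. Background of the EZH2 antibody alone and EZH2 bound without its mark both remain open as explanations: of 88 such genes with EZH2 and no H3K27me3 in DMSO, 84 (95.5%, 88.8 to 98.7) had EZH2 again in CPI-0209, which either could give. A control antibody or cells without EZH2 would be needed, and none was analysed here.

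Intervals within a list overlapped, 44516 of them with an earlier interval of their list. Splitting into 2 sets with gaps of at least 800 bp failed for 0 of the 32283 groups of 2 or more neighbouring intervals. It failed for 245 of 16716 groups in a list constructed from 3 sets and thinned to at most 2 intervals over a position, so 2 combined sets are consistent with all 4 lists. Applying 2 settings of the caller to the same reads stays open: 1 of 2 overlapping intervals held the other in 58.9% of pairs in EZH2 CPI-0209, up to 86.7% in H3K27me3 CPI-0209, and settings that differ in more than gap size or threshold could give the rest. What the sets are, such as separate libraries or the 4 and 8 days that the labels mention, is not stated, and no biological explanation was tested.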
